A study of Mus musculus with 6 samples.

How the data were processed

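Single cells were measured from mice that carried tumors of EMT6, a mouse mammary carcinoma cell line, in animals labelled Cysltr1-deficient and in BALB/c controls labelled WT. Cysltr1 encodes a receptor for cysteinyl leukotrienes, lipid mediators made by myeloid cells. Bone marrow cells were enriched for hematopoietic progenitors and cells of spleen and tumor for CD45, both magnetically, per the labels' protocols. There were 6 libraries, 1 for each of 3 tissues and 2 genotypes, each from a pool of 3 mice. Whether the tissues of a genotype came from the same mice is not stated, so tissues were not used as replicates.

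The deposited matrices hold UMI counts per gene and barcode as whole numbers, and every barcode in them had at least 500 UMIs. The submitters' processing notes name Cell Ranger 6.0.0 and the mouse build mm10, whereas the matrices were written by Cell Ranger 6.1.0 per the file headers. The labels' protocols name both a 5' and a 3' v3 kit, so the end of the transcript that was read is not settled. Each library listed 32285 genes. In 3 libraries 19 antibody features were listed as well, with 1 to 3 counts in each library, and were left out. Gene positions were taken from the GENCODE annotation of the same build by gene ID.

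Barcodes were kept with at least 300 genes, at least 500 UMIs and at most 10% of UMIs from mitochondrial genes. Doublets were scored per library against simulated doublets by the method of Scrublet, and the highest scores were removed at 0.8% of barcodes per 1000 barcodes. Counts were scaled to 10000 per cell and log-transformed. The WT and deficient cells of a tissue were clustered together, without batch integration, on 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1 with 10 iterations. Immunoglobulin and T cell receptor segments, sex-linked genes and Cysltr1 took no part in clustering.

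Clusters were named from markers of cell types that were fixed, with the tests, filters, gene lists, alternatives and the rule for naming genes, before the data were examined. A name needed at least 3 detected markers, each in at least 10% of the cluster's cells and 1.5-fold above the median cluster. It also needed more markers of its own class than of any other class among the cluster's 10 leading genes, so a tie left the cluster unnamed. A cluster whose median UMI count was under 0.333 of its library's also needed a mean marker ratio of at least 8-fold. These naming thresholds were set after the data were seen, and the share of unnamed clusters is given for each library. The same holds for grouping tumor clusters by Ptprc, the gene of CD45, under 50 CPM, and for counting unnamed clusters of at least 20 cells as sources of free RNA.

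UMIs were summed per library and class for classes with at least 100 cells in both libraries, and expressed as CPM of the class sum, counts scaled to the same total over all genes. Ratios of the library labelled deficient to the library labelled WT were taken on the log2 scale with a pseudocount of 1 CPM. Genes were compared within limits of at least 100 UMIs over both libraries, a mean of at least 50 CPM, and at least 20% of the level in the tissue's highest class, a guard against free RNA. Named genes were the 5 highest and 5 lowest ratios in the 3 largest classes of a tissue, at least 1.5-fold apart with exact Poisson intervals that did not overlap. Ribosomal, mitochondrial, haemoglobin, receptor segment, sex-linked and provisional genes were not named. Up to 4 members of each gene list outside the central 95% of random lists were named too. Genes among the 10 leading genes of a class's own clusters were not read as differences within it. A few single genes that the rule would name are not reported here. The rule on leading genes kept out of the report, but not out of the alternative settings, Retnlg in the neutrophil classes, Ifi27l2a in marrow monocytes, and H2-Eb1, H2-Ab1 and Cd74 in tumor monocytes. For Cd74 and H2-Eb1 in tumor monocytes the numbers of cells with a UMI are given, to describe the mix of cells.

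For 31 gene lists, the median log2 ratio of at least 5 members with 30 or more UMIs was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. With 1 library per tissue and genotype no difference has a replicate check and no test was run. The 95% intervals (exact Poisson for UMIs, Clopper-Pearson for shares) cover counting error only, and so does the floor of 3 counts used where a library had 0. On simulated data with 100 genes changed 3-fold and 100 changed 2-fold, 100% were recovered past 1.5-fold and 0 unchanged genes passed it, over 2544 genes in marrow progenitors, 2759 in spleen T cells and 2487 in tumor neutrophils. The simulated counts had Poisson error only, around a shared mean per gene, and the guard against free RNA was off. They check the calculation and hold no variation between libraries, mice or cells, so they cannot show how often single libraries differ without cause.

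Alternatives were looser and stricter cell filters, doublets kept, Leiden resolutions of 0.5 and 2, another CPM denominator, median-of-ratios scaling, a mean over cells, a pseudocount of 10 CPM, other minimum counts, no guard against free RNA, cells thinned to 1000 UMIs, a 2-fold threshold across tissues and shares over fewer cells. Leaving out a tumor neutrophil cluster or a single macrophage was chosen after seeing the data. Cells of a class were also drawn at random to the same number in each narrow bin of UMIs per cell in both libraries, a setting likewise added after seeing the data; deep cells of a shallow library may differ in kind from equally deep cells of the other. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.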

Results

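Transcripts were counted in cells of bone marrow, spleen and tumor from mice bearing EMT6 mammary tumors, with 1 library per tissue from mice labelled Cysltr1-deficient and 1 from mice labelled WT. Marrow libraries held 5852 (WT) and 6638 (deficient) barcodes with 75873784 and 47481894 UMIs. Spleen libraries held 9130 and 8407 barcodes with 41799544 and 40377940 UMIs, and tumor libraries 9740 and 6874 barcodes with 73393630 and 54569639 UMIs. After filtering, 5011 and 6054 marrow cells, 8307 and 7702 spleen cells, and 7929 and 5992 tumor cells were kept. Median UMIs per kept cell were 12700 and 6302 in marrow, 2916 and 3629 in spleen, and 3024 and 2315 in tumor. The comparison within each tissue asks how cell classes and their transcripts differed between the labelled genotypes. No difference has a replicate check, and intervals are 95% counting intervals.

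Cysltr1 (ENSMUSG00000052821, chromosome X, 106574346 to 106603679, minus strand, mm10), the targeted gene, was counted in every library and ran against the label in marrow and spleen. In marrow it was at 4.73 CPM (4.23 to 5.27, 326 UMIs) in the library labelled WT and at 24.5 CPM (23.1 to 26.0, 1055 UMIs) in the library labelled deficient, a ratio of 5.18 (4.57 to 5.89). Spleen had 6.88 CPM (250 UMIs) against 33.3 CPM (1180 UMIs), a ratio of 4.84 (4.22 to 5.57). Tumor went the other way, with 9.79 CPM (587 UMIs) against 7.03 CPM (335 UMIs), a ratio of 0.718 (0.626 to 0.822). In cells thinned to 1000 UMIs the ratios were 6.50 in marrow, 11.7 in spleen and 0.907 (0.648 to 1.26) in tumor. The labels do not give the deleted part of the gene, and a tag outside the deleted part checks nothing. Because of this, every direction below is drawn between libraries as labelled.

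Neutrophils had the highest level of Cysltr1 among named classes with at least 50 cells in the marrow and spleen libraries labelled deficient. Spleen neutrophils had 0.486 CPM (3 UMIs) in the library labelled WT and 172 CPM (157 to 188, 489 UMIs) in the library labelled deficient, a ratio of 354 with a counting interval of 121 to 1725. A Cysltr1 UMI was seen in 0.0847% and 31.1% of these cells at median depths of 2214.5 and 2337 UMIs. Spleen B cells, which serve as background, had a UMI in 0.0818% and 0.404% of cells at median depths of 2672.5 and 3399. Marrow neutrophils had 0 UMIs against 186 CPM, at least 28.1-fold higher, and immature marrow neutrophils 0 against 43.7 CPM, at least 53.5-fold higher. Monocytes were higher in the libraries labelled deficient in marrow (24.3 against 62.1 CPM, ratio 2.56) and spleen (37.6 against 95.7 CPM, ratio 2.55) and lower in tumor (52.9 against 23.4 CPM, ratio 0.442). In thinned cells the monocyte ratios were 2.87 in marrow, 1.32 (0.361 to 5.27) in spleen and 0.304 in tumor. Conventional dendritic cells 2 of spleen were near equal, at 39.3 against 44.7 CPM, a ratio of 1.14 (0.884 to 1.46), and spleen T cells were at 2.80 against 21.5 CPM, a ratio of 7.70 (5.16 to 12.0). Tumor macrophages were lower as well, at 58.5 against 27.1 CPM, but tumor neutrophils were higher, at 8.09 against 19.3 CPM, a ratio of 2.38 (1.28 to 4.70) and of 1.77 (0.705 to 5.01) in thinned cells. The unnamed tumor cluster 6 was higher too, at 20.5 against 96.0 CPM. Fndc3c1 (ENSMUSG00000033737, chromosome X, 106420041 to 106485401), a nearby gene of a fibronectin type III domain protein, had 0 UMIs in all 3 libraries labelled WT and 212, 633 and 179 UMIs in the marrow, spleen and tumor libraries labelled deficient. In spleen neutrophils it reached 157 CPM (143 to 173), at least 324-fold higher.

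**Figure D1:**
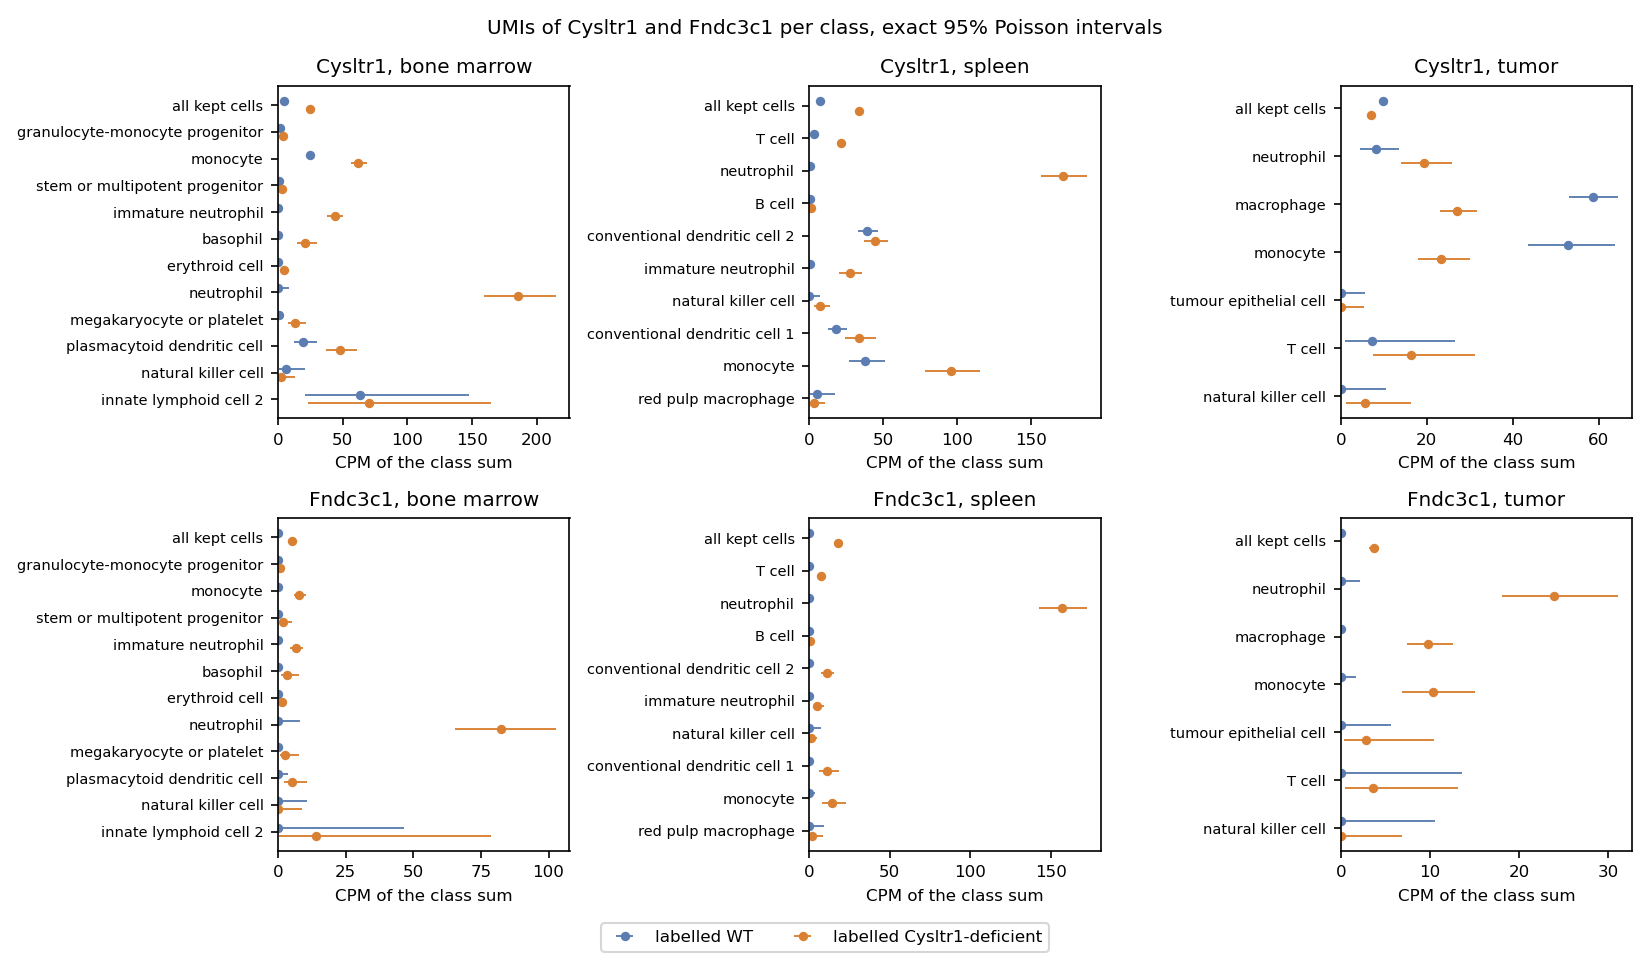
UMIs of Cysltr1 (top) and Fndc3c1 (bottom) as CPM of the class sum, for each named class and for all kept cells of a tissue. Points are single libraries, bars are exact 95% Poisson intervals, and Fndc3c1 lies at 0 in every class of the libraries labelled WT while spleen neutrophils of the library labelled deficient reach 157 CPM.

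In bone marrow, progenitor classes were smaller and neutrophil classes larger in the library labelled deficient. Granulocyte-monocyte progenitors made up 24.4% (23.2 to 25.6) of cells in the library labelled WT and 15.05% (14.2 to 16.0) in the other, and stem or multipotent progenitors 8.76% and 4.51%. Immature neutrophils were at 7.22% and 16.6%, a ratio of 2.30 (2.05 to 2.58), and mature neutrophils at 2.69% and 8.46%, a ratio of 3.14 (2.61 to 3.78). Monocytes were at 11.4% and 14.6%, plasmacytoid dendritic cells at 1.78% and 4.39%, and eosinophils at 1.497% and 0.380%. Unnamed clusters held 28.1% and 20.1% of cells. The marrow had been enriched for progenitors and its median depth differed between the libraries by a ratio of 0.496, both of which can set these shares. Values within marrow classes were therefore also taken in cells drawn to equal UMIs per cell in both libraries.

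Within granulocyte-monocyte progenitors few genes stood apart. Glo1, which encodes an enzyme that detoxifies methylglyoxal, was 2.36-fold higher (119 against 283 CPM) in the library labelled deficient. Rtf2, a replication termination factor gene, was lower (141 against 76.4 CPM, log2 ratio -0.88), and so were the linker histone gene Hist1h1b (184 against 109 CPM, -0.76), Eif4ebp2 (-0.60) and Eno1 (-0.59). In all, 1 gene was at least 2-fold higher and 4 lower among 2406 within limits, the 4 being kappa light chain variable genes with 0 UMIs in the library labelled deficient. Interferon gamma induced genes had a median of 0.24 (2 of 13 at least 1.5-fold higher, 0 lower; Igtp 3.53 against 5.997 CPM), type I interferon response genes 0.14 (1 of 17 higher) and tissue macrophage genes 0.25 (2 of 11 higher). In drawn cells Glo1 was at 1.37, Rtf2 at -0.92 and the interferon lists at 0.32 and 0.20, but tissue macrophage genes at -0.0024. Leukotriene genes had a median of 0.09 (-0.25 in drawn cells) and azurophil granule genes 0.11 (-0.22). Immediate early and heat shock genes had a median of -0.20 (0.16 in drawn cells), with 3 of 19 lower, among them the chaperone genes Hspa1a (11.7 against 1.05 CPM) and Hspa1b (14.3 against 1.999 CPM). Cluster 2 held the largest part of these cells in the library labelled WT and cluster 0 in the other.

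In marrow monocytes the type I interferon genes were higher in the library labelled deficient over all cells but not in cells drawn to equal UMIs. Of 23 measured members 17 were at least 1.5-fold higher and 0 lower, with a median of 0.80 (0.051 in drawn cells, 1 of 18 higher and 2 lower), among them Rtp4 (2.16 against 18.1 CPM), Isg15 (8.23 against 38.9 CPM) and Ifi44 (6.58 against 30.3 CPM). Pira2, a paired immunoglobulin-like receptor gene, was at 61.2 against 156 CPM (1.33, and 0.65 in drawn cells), and the lectin gene Clec4a3 at 40.6 against 85.9 CPM (1.06, and -0.49). Lower in all cells and in drawn cells were Chil3, a chitinase-like gene (398 against 109 CPM; -1.86 and -3.18), the proteoglycan gene Vcan (88.0 against 30.5 CPM), Rnase2a (-0.86 and -0.43) and Rtf2 (-0.84 and -1.14). MHC class II genes had a median of 0.45 (3 of 9 higher, with Cd74 at 3.91 against 28.7 CPM), MHC class I genes 0.36 and interferon gamma induced genes 0.22 (5 of 11 higher), against 0.39, 0.22 and 0.28 in drawn cells. Cd74 was low in both libraries, and list members were not held to the guard against free RNA. RNA of other cells was not tested as a source of these class II counts, and drawing cells to equal UMIs does not address it. The interferon gamma median ran from 0.16 to 0.65 over the settings tried. Hypoxia and glycolysis genes had a median of -0.25 (3 of 20 lower; Gapdh 605 against 382 CPM) and cell cycle genes -0.20, against 0.10 and 0.49 in drawn cells. There were 5 genes at least 2-fold higher and 2 lower among 2887 (20 and 21 among 2873 in drawn cells), and 14 of 24 lists lay outside the central 95%. The mature neutrophil list was at -0.53 but at 0.15 with doublets kept, and clusters 7 and 8 led the class in the WT and deficient libraries.

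Many values within immature neutrophils of marrow had opposite signs over all cells and in cells drawn to equal UMIs. The ratio of median UMIs in this class was 0.407. Over all cells Pira2 was at 27.8 against 90.6 CPM (1.67), the formyl peptide receptor gene Fpr1 at 55.6 against 125 CPM (1.15) and Timp2 at 51.8 against 99.0 CPM (0.92), but in drawn cells they were at -0.20, -1.12 and -1.78. Cell cycle genes had a median of -0.46 (0.79 in drawn cells), with 10 of 28 lower and 0 higher, among them Tuba1b (215 against 132 CPM) and Mcm5 (84.8 against 52.0 CPM), and Hist1h1b was at 227 against 77.4 CPM (-1.54, and -0.61 in drawn cells). Type I interferon genes had a median of 0.44 (8 of 21 higher; Ifi27l2a 33.3 against 129 CPM) and chemokine receptor genes 0.47 (3 of 8 higher; Cxcr2 149 against 232 CPM), against -0.37 and -0.66 in drawn cells. Suppressive myeloid genes had a median of 0.50 (4 of 11 higher; Clec4d 13.9 against 30.5 CPM), from -1.29 to 0.670 over the settings tried, and mature neutrophil genes 0.30 (3 of 19 higher), from -1.24 to 0.405, both lowest in drawn cells. Stfa2 (-0.89) and Stfa3 (-0.82), near-identical cystatin genes whose counts are uncertain, were lower, as was Cbx3 (-0.87, but 0.27 in drawn cells). Genes at least 2-fold apart numbered 2 higher and 1 lower among 1516, but 12 and 39 among 1498 in drawn cells. Cluster 11 led the class in the library labelled WT and cluster 3 in the other.

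**Figure D2:**
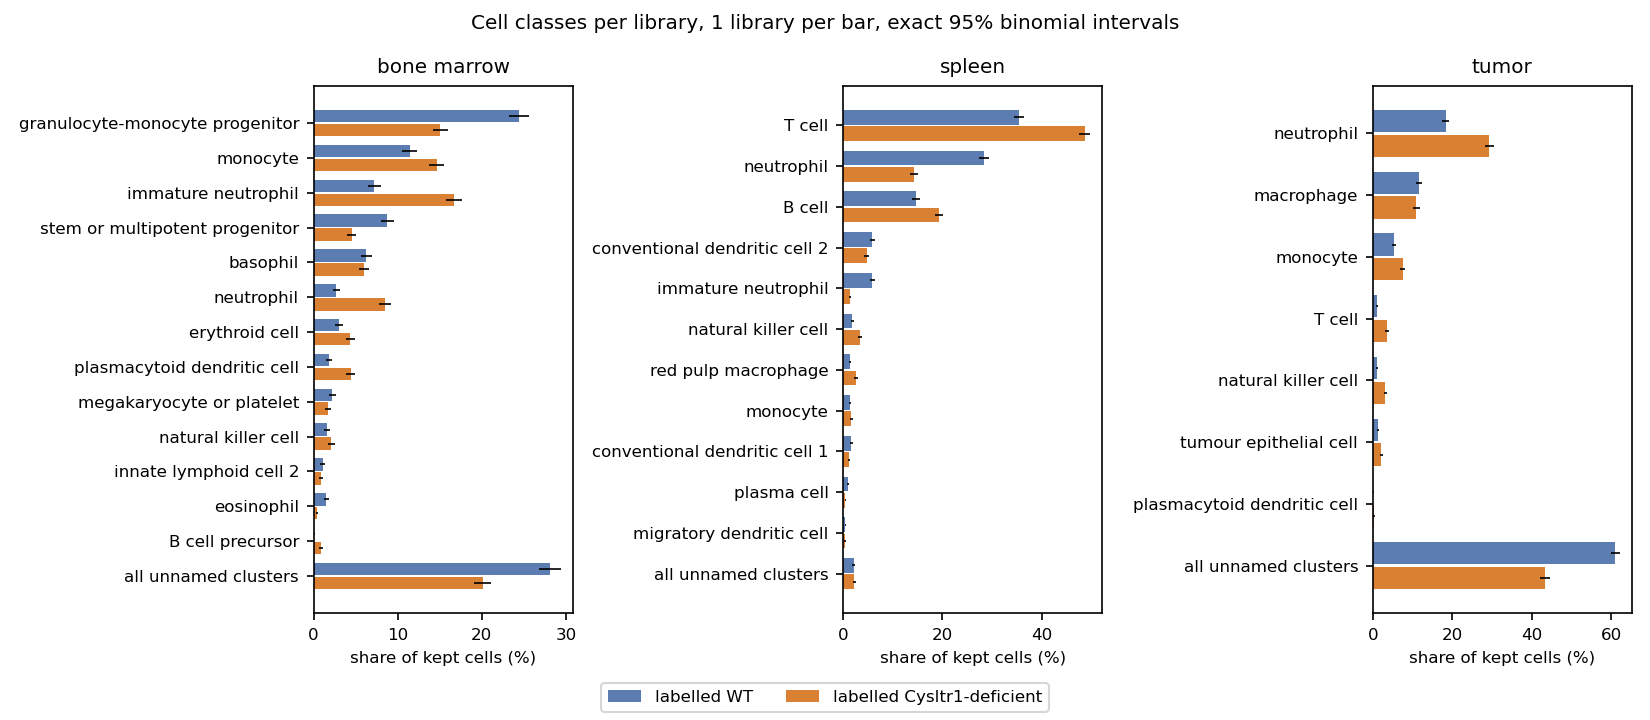
Share of kept cells (%) in each named class and in all unnamed clusters together, for the library labelled WT and the library labelled Cysltr1-deficient of each tissue. Bars are single libraries and error bars exact 95% binomial intervals; neutrophils are at 2.69% and 8.46% in marrow, 28.4% and 14.3% in spleen and 18.3% and 29.3% in tumor.

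Spleen had a lower share of neutrophils and higher shares of lymphocytes in the library labelled deficient. Neutrophils were at 28.4% (27.5 to 29.4) and 14.3% (13.5 to 15.1), a ratio of 0.502 (0.470 to 0.535), and immature neutrophils at 5.83% and 1.38%. T cells were at 35.5% and 48.7%, B cells at 14.7% and 19.3%, natural killer cells at 1.78% and 3.41%, and red pulp macrophages, which clear aged red cells, at 1.36% and 2.53%. Of the T cells, 33.5% and 35.8% were CD8 T cells, 10.9% and 11.5% CD4 T cells, 16.8% and 13.2% regulatory T cells, and 38.8% and 39.5% were in an unnamed T cell cluster. Conventional dendritic cells 2 were at 5.89% and 4.75%. Unnamed clusters held 2.14% and 2.21%. The cells had been enriched for CD45, and a share is relative to all other classes.

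Spleen neutrophils of the library labelled deficient had higher interferon transcripts and lower granule transcripts. Among genes within limits, beyond Fndc3c1 and Cysltr1, the highest ratios were those of the chemokine gene Cxcl10 (11.5 against 91.8 CPM, 7.43-fold), the interferon-induced GTPase gene Ifi47 (29.0 against 186 CPM, 6.23-fold) and Cd274, which encodes PD-L1, a ligand that restrains T cells (34.1 against 171 CPM, 4.89-fold). Interferon gamma induced genes had a median of 1.53, with 13 of 15 higher and 1 lower, among them Gbp4 (1.46 against 26.4 CPM) and Gbp5 (5.34 against 63.3 CPM). Type I interferon genes had a median of 0.79 (17 of 25 higher; Ifit3 14.2 against 76.0 CPM), MHC class I genes 0.77 (9 of 13 higher), NF-kB target and cytokine genes 0.60 (10 of 19 higher; Ccl4 156 against 610 CPM) and suppressive myeloid genes 0.50 (7 of 14 higher, 2 lower; Ptgs2 173 against 341 CPM). Secondary and tertiary granule genes had a median of -1.54, with 10 of 11 lower, among them Camp (296 against 56.0 CPM), Ltf (283 against 58.1 CPM) and Cd177 (423 against 130 CPM). Mmp8, a neutrophil collagenase gene, was at 1089 against 338 CPM (-1.69) and Ly6g, a surface marker gene of neutrophils, at 855 against 304 CPM (-1.49).

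Leukotriene genes had a median of -0.33 in spleen neutrophils, with 4 of 10 lower and 1 higher, the targeted gene Cysltr1 itself. Alox5ap, which helps 5-lipoxygenase to start leukotriene synthesis, was at 4333 against 2583 CPM, and Ggt1, which converts one cysteinyl leukotriene to another, at 31.4 against 7.74 CPM. Hypoxia and glycolysis genes had a median of -0.31 (5 of 20 lower, 2 higher; Ldha 523 against 325 CPM). Immediate early genes had a median of 0.25, among them Egr1 (640 against 1428 CPM). Among 1929 genes 34 were at least 2-fold higher and 15 lower. Immature neutrophils, which carry granule transcripts, were fewer in the same library (5.83% against 1.38%), and cluster 4 held 42.3% and 21.4% of the neutrophils.

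T cells of spleen were apart in several single genes. Sfi1, a centrosome gene, was 3.10-fold higher (59.8 against 187 CPM) in the library labelled deficient, Nsg2 was at 39.4 against 80.9 CPM (1.02) and Glo1 at 92.7 against 187 CPM. Dnah8 (0.98) overlaps an end of Glo1 on chromosome 17 but lies on the opposite strand. Whether these genes share reads was not tested. Arl2bp was at 92.8 against 16.4 CPM (-2.43), Tmem181a at 87.7 against 34.5 CPM (-1.32), Rtf2 at 132 against 59.7 CPM (-1.13) and Prelid2 at 92.4 against 44.4 CPM (-1.04). H2-Q6 was higher (237 against 458 CPM) and H2-Q7 lower (242 against 52.6 CPM), near-identical MHC class I genes whose counts are uncertain. Cytotoxic genes had a median of 0.13 (6 of 15 higher, 1 lower; Ccl4 29.8 against 64.1 CPM, Eomes 17.7 against 35.7 CPM) and regulatory T cell genes -0.22 (0 of 10 past 1.5-fold; Tnfrsf18 143 against 95.5 CPM), against 0.59 and 0.15 in cells drawn to equal UMIs. Interferon gamma induced genes were at 0.21 (1 of 16 higher) and type I interferon genes at 0.14. Heat shock genes were at -0.14 (Hspa1b 19.8 against 1.92 CPM). Lists of neutrophil granule genes had a median of -1.95 here, where the neutrophil transcript S100a8 was at 270 against 84.1 CPM, 0.389% and 0.144% of its level in neutrophils. Among 2602 genes 4 were at least 2-fold higher and 6 lower.

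Spleen B cells of the library labelled deficient had higher interferon gamma induced genes, with a median of 0.54 and 7 of 14 higher, among them Gbp2 (14.4 against 28.2 CPM) and the transcription factor gene Irf1 (73.7 against 130.3 CPM). B cell activation genes had a median of 0.20 (3 of 16 higher, 1 lower; Cd86 34.2 against 58.3 CPM), MHC class I genes 0.24 and suppressive genes 0.27 (Cd274 71.2 against 107 CPM). Pcp4, a calmodulin-binding protein gene, was at 19.5 against 86.2 CPM (2.09), Sfi1 at 66.0 against 238 CPM (1.83) and Glo1 at 66.5 against 134 CPM (0.99). Rtf2 was at 141 against 66.4 CPM (-1.07) and the RNA-binding protein gene Zfp36l2 at 769 against 483 CPM (-0.67). The neutrophil transcript S100a8 was lower here too (269 against 89.3 CPM, 0.387% and 0.153% of its level in neutrophils), as were secondary and tertiary granule genes, with a median of -1.997. There were 4 genes at least 2-fold higher and 5 lower among 2732.

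Neutrophils, T cells and natural killer cells held larger shares of the tumor library labelled deficient. Neutrophils were at 18.3% (17.5 to 19.2) and 29.3% (28.1 to 30.4) in the libraries labelled WT and deficient, a ratio of 1.60. T cells were at 1.15% and 3.47%, natural killer cells at 1.02% and 3.19%, monocytes at 5.42% and 7.49%, and macrophages at 11.7% and 10.9%. Unnamed clusters held 61.0% and 43.2% of cells, and clusters with Ptprc under 50 CPM, which lack the transcript used for enrichment, 44.9% and 31.7%. Every share in the tumor moves with how many such cells passed the enrichment. Over the classes left after taking out tumor and unnamed clusters the neutrophil ratio was 1.10 and the monocyte ratio 0.954 in place of 1.38. Without neutrophil cluster 8 the neutrophil ratio was 1.21.

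Tumor neutrophils of the library labelled deficient had higher interferon gamma induced genes, with a median of 1.55 and 17 of 18 members higher. Socs1, a feedback inhibitor gene of cytokine signalling, was 4.45-fold higher (53.2 against 240 CPM), Ifi47 was at 184 against 611 CPM (1.72), the adhesion molecule gene Icam1 at 115 against 372 CPM (1.68), Cxcl10 at 238 against 751 CPM (1.65) and the GTPase gene Igtp at 47.4 against 150.3 CPM (1.64). Type I interferon genes had a median of 0.52 (10 of 26 higher; Oasl2 75.1 against 206 CPM), NF-kB target and cytokine genes 0.51 (9 of 20 higher; Sod2 488 against 1098 CPM) and MHC class I genes 0.48 (5 of 13 higher; Tap1 86.7 against 163 CPM). The MHC class I median ran from 0.21 to 0.62 over the settings tried. Suppressive myeloid genes had a median of 0.29 (3 of 16 higher, 1 lower, with Clec4n at 121 against 231 CPM). MHC class II genes had a median of 1.32 (5 of 8 higher), and the sum of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 was at 4.52% of its level in monocytes. Granule genes had a median of -0.68 (6 of 10 lower), Mmp8 was at 97.6 against 33.8 CPM and the antibacterial peptidoglycan receptor gene Pglyrp1 at 359 against 157 CPM (-1.19). Ngp was at 169 against 8.56 CPM, but 3 cells held 51.2% of its 293 UMIs in the library labelled WT. The ratios lie about a median of -0.16 over all genes of the class.

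Cluster 8 held 16.5% of the tumor neutrophils in the library labelled WT and 36.7% in the other, and the largest part of the class was in cluster 3 in the former and cluster 8 in the latter. There were 34 genes at least 2-fold higher and 5 lower among 2298, but 5 higher and 6 lower without cluster 8, of which 8 were among the same genes. Without that cluster the interferon gamma median was 0.95, Socs1 was at 45.2 against 90.6 CPM (0.99), Igtp at 31.6 against 79.6 CPM (1.31), Cxcl10 at 37.3 against 102 CPM (1.43) and Icam1 at 73.3 against 108 CPM (0.55). With doublets kept 3 genes were at least 2-fold higher and 5 lower.

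**Figure D3:**
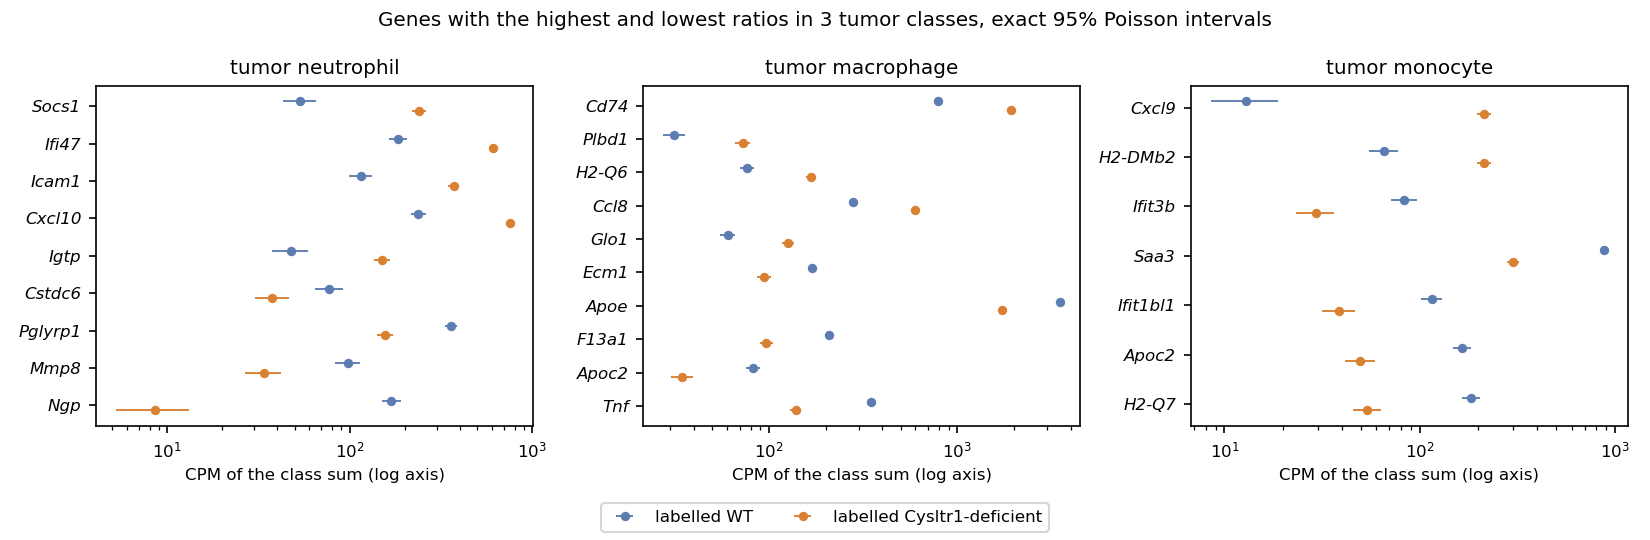
CPM of the class sum (log axis) of the genes with the highest and lowest ratios, within the limits on UMIs, CPM and free RNA, in tumor neutrophils, macrophages and monocytes, without genes that lead a cluster of the class. Points are single libraries and bars exact 95% Poisson intervals; Cxcl9 in monocytes is at 12.9 CPM in the library labelled WT and 214 CPM in the library labelled deficient.

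Tumor macrophages of the library labelled deficient had higher MHC class II genes and lower Tnf, Apoc2 and Apoe. The class II list had a median of 1.13, with 6 of 9 higher and 0 lower, among them Cd74, which encodes the invariant chain of class II molecules (788 against 1924 CPM), H2-Eb1 (84.2 against 210 CPM) and H2-Aa (158 against 352 CPM). Members of lists were not held to the guard against free RNA. The class II list was higher in tumor monocytes too, from 1.48 to 1.68 over the settings tried, and RNA of those cells was not tested as a source here. Ccl8, a chemokine gene, was at 280 against 599 CPM (1.09) and Plbd1 at 31.5 against 72.6 CPM (1.18). The cytokine gene Tnf was at 348 against 139 CPM (-1.32), the apolipoprotein genes Apoc2 and Apoe at 82.5 against 34.7 CPM (-1.23) and 3486 against 1724 CPM (-1.02), and F13a1, a coagulation factor gene, at 210 against 97.1 CPM (-1.10). Interferon gamma induced genes had a median of 0.52 (7 of 17 higher; Gbp5 10.2 against 21.4 CPM) and type I interferon genes 0.50 (4 of 26 higher; Isg15 215 against 342 CPM). Tissue macrophage genes had a median of -0.15 (3 of 18 lower, 2 higher; Cd163 29.7 against 16.8 CPM; 0.021 with doublets kept) and stromal genes -0.71 (Col1a2 92.3 against 38.1 CPM). There were 6 genes at least 2-fold higher and 4 lower among 2600. The granule list was at 0.88, but 1 cell held all 431 Camp UMIs of the library labelled deficient, and without it the median was 0.10.

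Tumor monocytes of the library labelled deficient had lower type I interferon genes and higher cell cycle genes. The interferon list had a median of -0.63, with 14 of 26 lower and 0 higher, among them the antiviral genes Ifit3 (317 against 126 CPM), Ifit2 (329 against 146 CPM) and Ifit3b (83.4 against 29.3 CPM). Cxcl9, a chemokine gene induced by interferon gamma, went the other way, 15.5-fold higher (12.9 against 214 CPM), with 27 UMIs in 10 of 430 cells and 577 UMIs in 77 of 449 cells. Cell cycle genes had a median of 0.61, from 0.24 to 0.64 over the settings tried, with 15 of 28 higher and 0 lower. Among them were Ube2c (44.3 against 84.3 CPM) and Birc5 (27.2 against 51.6 CPM). MHC class II genes had a median of 1.58 (8 of 11 higher, 1 lower; H2-DMb2 65.3 against 214 CPM), and 4 members of that list lead the only cluster of the class. Apoc2 was at 165 against 49.8 CPM (-1.71), Apoe at 4133 against 1791 CPM (-1.21) and the acute phase gene Saa3 at 881 against 300 CPM (-1.55). Cd83 (79.1 against 178 CPM), Cd86 (110 against 195 CPM) and the chemokine receptor gene Ccr7 (43.4 against 79.5 CPM), all carried by activated dendritic cells, were higher, and no tumor cluster was named conventional dendritic cell. Cd74 UMIs were seen in 197 of 430 cells and in 386 of 449 cells, and H2-Eb1 UMIs in 78 and 263 of them. A different mix of cells in this class was not separated from a change within monocytes. The neutrophil transcript S100a8 was at 2126 against 732 CPM. No tumor cluster was named monocyte at Leiden resolution 2.0 or with the stricter cell filter, so the values of this class were not measured there. Among 2636 genes 21 were at least 2-fold higher and 24 lower.

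Some genes stood apart the same way in a class of every tissue that held it. Neutrophils shared 6 genes at least 1.5-fold higher among 860, against 0.0508 for independent lists, among them Hcar2, Ccrl2, Csrnp1, the inflammasome gene Nlrp3 and the interferon-induced gene Rtp4 (1.11, 0.74 and 0.80 in marrow, spleen and tumor). They shared 3 lower genes, Prok2 (-0.85, -1.28 and -0.74), Cstdc5 and Stfa2, against 0.0181. Monocytes shared Pira2 (1.33, 0.73 and 1.26) and Glo1 (0.93, 0.77 and 0.71) as higher and Rtf2 (-0.84, -0.95 and -0.83) as lower among 1845 genes, against 0.0114 and 0.00338. Immature neutrophils of marrow and spleen shared 0 higher genes and 4 lower ones, Dtymk, Dbi, Rtf2 and Klf2, among 1265, against 0.252. At 2-fold no gene was shared in any of these classes. The tissues of a genotype may come from the same mice, so these counts are not replication. In cells drawn to equal UMIs 4 of the 6 higher and 2 of the 3 lower neutrophil genes stayed past 1.5-fold in every tissue, all 3 monocyte genes did, and of the immature neutrophil genes only Rtf2.

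Over all 20 classes compared, interferon gamma induced genes had a median above 0 in 20, from 0.06 to 2.10, and lay above the central 95% of random lists in 15. Type I interferon genes lay above it in 17 and below it in 1, the tumor monocytes. MHC class I genes had a positive median in 20 classes and lay above the central 95% in 14. MHC class II genes lay above it in 8 of 16 classes and below it in 5. Azurophil granule genes lay below it in 9 of 11 classes and above it in 1, the marrow granulocyte-monocyte progenitors; the 9 include spleen T cells, where S100a8 of neutrophils was also lower. In cells drawn to equal UMIs the interferon gamma median was above 0 in 16 of 16 classes, from 0.019 to 1.81, and the type I median in 16 of 20, while the azurophil median was above 0 in 4 of 7 marrow classes. Lying outside the central 95% was common, from 4 of 19 lists in marrow megakaryocytes or platelets to 11 of 16 in tumour epithelial cells. Random lists drew each gene independently, so lists whose members move together can lie outside more often. The 20 classes come from 1 pair of libraries per tissue. Classes of a tissue share mice and free RNA, so they are not independent observations. List members were not held to the guard against free RNA. Tumour epithelial cells are among the 20 classes, and if they are EMT6 cells the labelled genotype is that of their host.

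**Figure D4:**
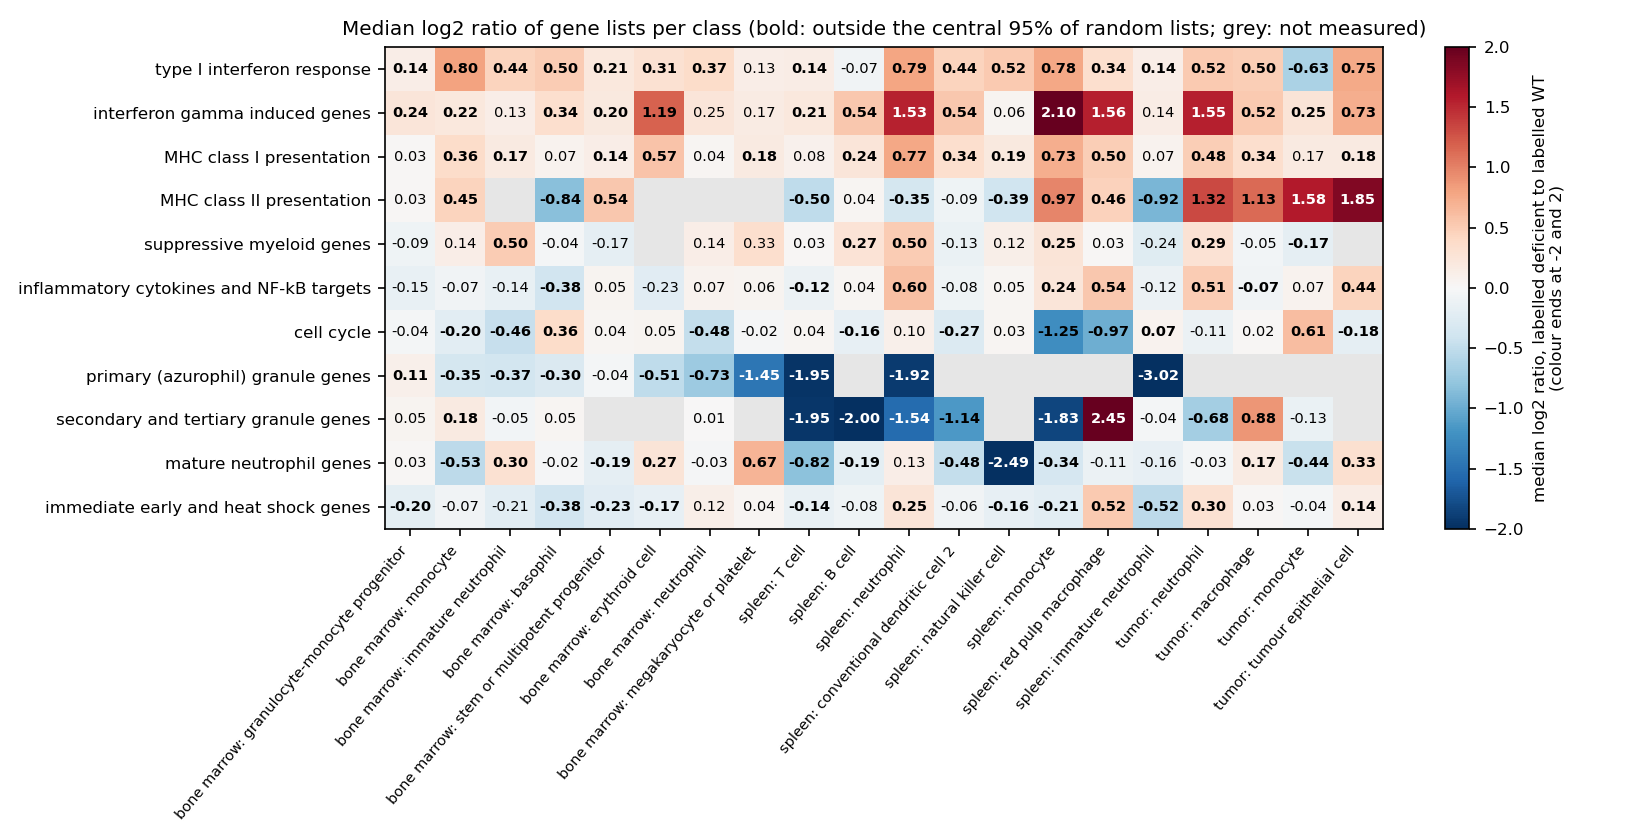
Median log2 ratio of the library labelled deficient to the library labelled WT for 11 of the 31 gene lists, chosen after their values were seen, in each compared class. Bold values lie outside the central 95% of random lists and grey marks lists not measured; the interferon gamma values run from 0.06 to 2.10, and cells are not drawn to equal UMIs.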

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

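All tests weighed in this part were chosen only after the results were seen. Several results went in opposite directions in different tissues, and none of these differences between tissues was tested. Immature neutrophils had a share ratio, labelled deficient to labelled WT, of 2.30 in marrow and 0.236 in spleen. Mature neutrophils were at 3.14 in marrow and 1.60 in tumor but at 0.502 in spleen. Cysltr1 in monocytes was at 2.56 in marrow and 2.55 in spleen (1.32, 0.361 to 5.27, in thinned cells) but at 0.442 in tumor. Cell cycle genes of monocytes had a median log2 ratio of 0.61 in tumor (0.24 to 0.64 over the settings tried) and -1.25 in spleen. In cells drawn to equal UMIs no tumor class was above 0.29 for this list and no spleen class below -0.94. The tumor monocyte class also differed between the libraries in its mix of cells with class II transcripts. Type I interferon genes of monocytes were at 0.80 in marrow and 0.78 in spleen but at -0.63 in tumor, against 0.051, 0.73 and -0.53 in cells drawn to equal UMIs per cell.

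Cysltr1 and the nearby gene Fndc3c1 were both high in spleen neutrophils of the library labelled deficient, where the targeted gene would be low if its counted part were deleted. RNA of other cells is argued against by the level of Fndc3c1 in these neutrophils, 157 CPM (143 to 173), since the next named class, the monocytes, had 14.1 CPM (8.03 to 22.8). A change over a wider part of chromosome X is argued against by 6 other measured genes within 1 Mb, Atrx, Magt1, Cox7b, Atp7a, Tlr13 and Pgk1, of which 0 were at least 2-fold higher (ratios 0.685 to 1.16). A candidate explanation is altered transcription of the modified Cysltr1 allele, reaching into the nearby gene: the 3 libraries labelled deficient held 1024 Fndc3c1 UMIs and the others 0. This cannot be told apart from any other inherited difference between the animals, because each tissue and genotype is a single pool of mice and the deleted part is not given.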

How the results depend on the processing

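The settings that draw cells to equal UMIs or leave out tumor neutrophil cluster 8 or the macrophage with the most Camp UMIs were chosen only after the results were seen; the others were fixed beforehand. Of 86 alternative values of share ratios 58 stayed within the counting interval, 27 moved and 1 reversed. Of 107 counts of genes 74 stayed within 1.5 times. Of 1027 list medians 801 stayed the same, 198 moved and 28 reversed, and of 1924 values of named genes 1574, 298 and 52. The cause of each move was not tested unless the setting itself gives it. Leiden resolution 0.5 left 3 results without a value, Leiden resolution 2.0 15, the stricter filter 16, a minimum of 100 UMIs 8 and the drawn cells 3. At resolution 0.5 named classes were lost. With a minimum of 100 UMIs and in drawn cells the classes were kept, but lists had too few measured members. Tumor monocytes made up 14 of the 15 at resolution 2.0 and 14 of the 16 with the stricter filter, as no tumor cluster was named monocyte there. The rest were lists with too few measured members in classes that were kept. These were the erythroid list of spleen T cells in both settings and the inhibitory receptor list of tumor neutrophils with the stricter filter. No analysis paired by tissue was run, since it is not stated whether the tissues of a genotype share mice, and no result comes from a test.

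Share ratios moved as follows. With the looser filter they were 0.716 for granulocyte-monocyte progenitors, 1.68 for marrow immature neutrophils, 1.04 for marrow monocytes, 0.805 for tumor macrophages and 1.75 for tumor neutrophils. The stricter filter gave 0.678, 1.86, 1.15, 0.837 and 1.82 for the same classes and 0.543 for spleen neutrophils. With doublets kept, granulocyte-monocyte progenitors were at 0.667, marrow immature neutrophils at 1.70, marrow monocytes at 1.03 and tumor neutrophils at 1.21. At Leiden resolution 0.5 granulocyte-monocyte progenitors were at 0.687, stem or multipotent progenitors at 0.602, marrow monocytes at 1.02 and tumor macrophages at 0.789, and at resolution 2.0 marrow monocytes were at 1.10 and tumor macrophages at 0.793. Without erythroid, tumor, stromal and unnamed clusters, granulocyte-monocyte progenitors were at 0.563, tumor macrophages at 0.646, tumor neutrophils at 1.10, tumor T cells at 2.09 and tumor natural killer cells at 2.15, and tumor monocytes reversed to 0.954. Without cluster 8 tumor neutrophils were at 1.21. The ratios of spleen T cells (1.36 to 1.39), B cells (1.31 to 1.32) and natural killer cells (1.92 to 1.97) kept to narrow ranges.

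Counts of genes at least 2-fold apart were also taken with no CPM minimum and at least 30 UMIs in place of 100, 2 choices changed together. They were then 33 in granulocyte-monocyte progenitors, 49 in marrow immature neutrophils, 50 in marrow monocytes, 60 in spleen B cells, 43 in spleen T cells, 151 in spleen neutrophils, 60 in tumor macrophages, 167 in tumor monocytes and 170 in tumor neutrophils, as more genes were counted. Without the guard against free RNA they were 6 in marrow immature neutrophils, 17 in marrow monocytes, 16 in spleen B cells and 16 in tumor macrophages. Granulocyte-monocyte progenitors had 1 with the looser filter, the stricter filter, doublets kept and resolution 2.0, and 3 with a mean over cells. Marrow immature neutrophils had 6 with the stricter filter, 8 at resolution 0.5 and 8 with a mean over cells. Marrow monocytes had 11 with the other CPM denominator, 11 with a mean over cells and 4 with a pseudocount of 10 CPM, which gave 5 in spleen B cells. Tumor macrophages had 5 with the looser filter, 6 at resolution 2.0 and 4 with a mean over cells. Tumor neutrophils had 8 with doublets kept (3 higher, 5 lower) and 11 without cluster 8 (5 higher, 6 lower), against 34 higher and 5 lower.

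Cysltr1 ratios in cells thinned to 1000 UMIs were 6.50 in marrow, 11.7 in spleen and 0.907 in tumor. Across tissues, 5 counts of shared genes moved to 0 at 2-fold. Reversed lists were prostanoid genes of marrow monocytes (-0.080) and B cell activation genes of tumor neutrophils (-0.0063) with a minimum of 100 UMIs, and secondary granule genes of marrow monocytes (-0.66) with the stricter filter. With doublets kept the mature neutrophil genes of marrow monocytes (0.15), lineage factors of marrow immature neutrophils (-0.027), and the NF-kB (0.13), tissue macrophage (0.021) and inhibitory receptor (0.086) lists of tumor macrophages reversed, as did erythroid genes of spleen T cells (-2.40), also with the looser filter (-0.99). With doublets kept G0s2 reversed in marrow monocytes (1.05), Ccl6 (-0.13), Csf1r (-0.12) and Egr1 (0.082) in marrow immature neutrophils, Hbb-bt (-2.79), Hbb-bs (-4.50), Hba-a2 (-2.71) and Hba-a1 (-2.64) in spleen T cells, and Il1b (-0.070) and Mki67 (0.016) in spleen B cells. Il10 of tumor monocytes reversed with a mean over cells (0.14). Depth limits the Cysltr1 ratios of single classes in thinned cells, as in spleen monocytes, at 1.32 with an interval of 0.361 to 5.27.

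Cells drawn to equal UMIs per cell moved the marrow most. Of 29 marrow list medians 5 stayed the same, 7 moved and 17 reversed, against 24, 11 and 1 of 36 in spleen and 26, 10 and 0 of 36 in tumor. Counts of genes at least 2-fold apart were 1 in granulocyte-monocyte progenitors, 51 in marrow immature neutrophils and 41 in marrow monocytes, and those of spleen and tumor stayed within 1.5 times. Reversed lists of granulocyte-monocyte progenitors were leukotriene (-0.25), tissue macrophage (-0.0024), azurophil granule (-0.22) and immediate early (0.16), and genes Alox5 (-0.23) and Egr1 (0.012). In marrow immature neutrophils the reversed lists were suppressive myeloid (-1.29), type I interferon (-0.37), chemokine receptor (-0.66), cell cycle (0.79), azurophil granule (0.74), mature neutrophil (-1.24), lineage factor (-0.19) and unfolded protein response (0.12). Reversed genes of that class were Pira2 (-0.20), Fpr1 (-1.12), Timp2 (-1.78), Retnlg (-1.93), Hacd4 (-0.96), Cbx3 (0.27), Prc1 (0.77), Clec4d (-2.90), Cd84 (-1.30), Arg2 (-1.29), Clec4e (-1.41), Ifi27l2a (-0.24), Rtp4 (-1.53), Isg15 (-0.46), Ddx60 (-0.65), Cxcr2 (-1.31), Ccr1 (-1.19), Tuba1b (0.34), Mcm5 (0.36), Ccnb1 (0.94), Mcm2 (0.37), Ccl6 (-1.06), Csf1r (-0.89), Cd69 (0.50) and Pdia4 (0.12). In marrow monocytes the reversed lists were hypoxia (0.10), cell cycle (0.49), azurophil granule (0.86), secondary granule (-1.39) and unfolded protein response (0.28), and the genes Ifi27l2a (-0.07), Clec4a3 (-0.49), Plbd1 (-0.69), Tbxas1 (-0.14), Gbp2 (-0.17), Ms4a3 (0.36), Prss57 (0.16), Camp (-3.23), Cd177 (-1.39), Lyz2 (-0.56), Batf3 (-0.11) and Id2 (-0.83). Of these genes Retnlg in marrow immature neutrophils and Ifi27l2a and Lyz2 in marrow monocytes are leading genes of clusters of their class, so they were not read as differences within it. In spleen, regulatory T cell genes of T cells (0.15) and Il1b (-0.25) and Rrm2 (0.13) of B cells reversed. The cause was not tested: depth and the stage of the cells are not separated by this draw.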

Other observations

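All tests weighed in this part were chosen only after the results were seen. Smaller classes of the libraries labelled deficient also had high interferon transcripts over all cells. Spleen monocytes had a median of 2.10 for interferon gamma induced genes (15 of 17 at least 1.5-fold higher, 0 lower), 0.78 for type I interferon genes (19 of 25 higher) and 0.97 for MHC class II genes, while the neutrophil transcript S100a8 was lower there (3831 against 574 CPM). Red pulp macrophages of spleen were at 1.56 (11 of 15 higher; 0.77 in cells drawn to equal UMIs), with higher S100a8 (1299 against 3804 CPM, 1.87% and 6.51% of the level in neutrophils, themselves at 1.53). Marrow erythroid cells were at 1.19 (6 of 7 higher), and tumour epithelial cells at 0.73 for interferon gamma and 0.75 for type I interferon genes. If the epithelial cells are of the EMT6 line, which was used in both libraries, the labelled genotype is that of the host animal. Marrow basophils, which release histamine and cytokines, were at 0.50 for type I interferon genes (0.32 in drawn cells), with cluster 15 leading the class in the library labelled WT and cluster 16 in the other.

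Some other lists also lay outside the central 95% of random lists. Stem and progenitor genes lay below it in 4 of 16 classes and above it in 0. Unfolded protein response genes lay below it in 5 of 20 classes and above it in 1, and oxidative stress genes below it in 6 and above it in 4. Type 2 cytokine genes lay inside it in all 3 classes where they were measured. Xist, which female cells transcribe, was at 95.6 to 496 CPM in the 6 libraries, and the Y-linked genes Ddx3y and Eif2s3y had 0 UMIs in each, while Uty and Kdm5d, also Y-linked, had 0 to 2.

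Rtf2, Sfi1, Pira2, Glo1 and H2-Q6 stood apart the same way over most measured classes of marrow and spleen, and were singled out after their values were seen. Rtf2 was at least 1.5-fold lower in 17 of 19 classes, and Sfi1, Pira2, Glo1 and H2-Q6 higher in 8 of 8, 9 of 9, 13 of 15 and 13 of 15, but in tumor Sfi1 was not measured and Glo1 and H2-Q6 passed in 2 of 4 classes each. A difference in depth is argued against as the whole source by cells drawn to equal UMIs per cell in both libraries of a class, where 58 of 63 class values, Pira2 in marrow left out, had intervals beyond 1 in the usual direction and the genes' median folds were 1.97 to 3.07. For Pira2 in marrow depth cannot be told apart from the labelled genotype, since only 1 of its 3 class values lay beyond 1 in drawn cells (log2 -0.20 in immature neutrophils in place of 1.67). RNA of other cells is argued against by 4 of the 5 genes being at least 1.5-fold apart in the class with their highest level, Rtf2 being 1.33-fold apart there. That is no independent check, since the genes were singled out for being apart in most classes, Sfi1 and Pira2 in all measured ones. A genetic difference of the animals outside Cysltr1 may be the source, but it cannot be told apart from the labelled genotype in these pools. That 0 of the 5 genes lie on chromosome X does not decide this, since most genes lie elsewhere. For H2-Q6 a shared count with H2-Q7 is a candidate explanation too. The sum of both genes was within 1.5-fold of equal in 9 of 13 classes. These include tumor monocytes, where H2-Q6 was 1.06-fold apart, and tumor neutrophils, where H2-Q7 was 1.05-fold apart. They also include tumour epithelial cells, where neither gene passed 1.5-fold, so these tumor classes show no exchange of counts.

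Interferon gamma induced genes were higher in tumor neutrophils of the library labelled deficient, with a median of 1.55. A shift of cells between clusters is argued against as the whole source by medians within the 3 neutrophil clusters of 0.74 at the lowest and 1.12 at the highest, although these stay below the value of the whole class, so the shift may add to it. RNA of other cells is argued against by 13 of the 17 higher members having at least 50 percent of their highest level in neutrophils, but it may account for the MHC class II genes there, whose sum was 4.52% of the level in monocytes with each gene's part of the sum at 0.863 to 1.21 of that in monocytes. A response to cell isolation may have added to it, since immediate early and heat shock genes had a median of 0.30 in these neutrophils. That list ran from 0.22 to 0.44 over the settings tried, while all genes of the class had a median of -0.16. In macrophages and monocytes such a response is argued against by list medians of 0.03 and -0.04, where interferon gamma medians were 0.52 and 0.25. A part from cell isolation in neutrophils, the labelled genotype, a difference between the tumors and any other difference between the 2 pools stay open.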
